A study of Mus musculus with 2 samples.

How the data were processed

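Gene expression was measured by RNA sequencing in lung tissue of C57BL/6 mice, in 1 control library and 1 library from PM2.5 exposure, grouped by the exposure the labels give. Per the labels' protocols, total RNA was extracted with TRIzol, polyadenylated mRNA was selected on oligo-dT beads and treated with DNase, and stranded libraries were made with a KAPA kit. They were sequenced on a HiSeq2500 in paired mode with reads of 125 bp. The submitters' processing notes name TopHat2 2.1.1, HTSeq 0.6.0 and the mouse genome build mm10. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited files hold raw read counts per Ensembl gene identifier, without normalization, and no row other than genes apart from 1 blank line in the PM2.5 file, which carries no count.

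Both files list 37315 identifiers. Symbols, coordinates, gene types and transcript lengths came from GENCODE release M21 on GRCm38, the assembly called mm10. A symbol was found for 35449 identifiers, and those without one took 0.199% of the control counts and 0.256% of the PM2.5 counts. The totals were 62788045 counts (control) and 57435027 counts (PM2.5). The 10 genes with most counts took 7.71% and 10.8% of them, and the mitochondrial genome 4.08% and 5.07%. Library sizes were scaled with edgeR 4.0.16 (TMM factors 0.923 and 1.08 on the totals), and CPM was computed from the scaled sizes.

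With 1 library per group no model of the variation between animals can be fitted, so no p-value or standard error is given. For each gene the ratio of CPM, PM2.5 over control, was computed with an exact 95% interval (Clopper-Pearson on the PM2.5 share of the counts of both libraries). The interval covers counting error only, since reads are not independent molecules and animals vary. A gene with no count in a library was set against a floor of 3 counts, which is 0.0517 CPM in the control library and 0.0482 CPM in the PM2.5 library. Genes with a mean of at least 1 CPM entered, and a gene was counted as higher or lower at 2-fold or more with an interval that excludes a ratio of 1. For list members the size was 1.5-fold.

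Before the data were examined, 51 gene lists for cell types, tissues and pathways were fixed. Each list of at least 5 measured genes was described by the median log2 ratio and its percentile among 10000 random lists of the same size, drawn from the same of 20 bins of mean CPM. Genes to be named were also fixed then: the 15 highest and 15 lowest by the interval bound nearest to a ratio of 1, without unnamed predicted genes and immunoglobulin or T cell receptor segments. Up to 4 leading members of each list were added, or its most abundant members where a list did not stand apart, and a set of 15 genes named whatever their values. Other genes, such as members that went against their list, abundant members of a list that stood apart, Marco, Spp1 and Gm13841, were chosen after their values were seen. Some genes that the rule takes are not reported here. Genes with near-identical copies, such as the H2-Q, Hba, Ear, Klra, Ighg, Ccl21 and ribosomal protein genes, and antisense or overlapping genes are uncertain, since the counting can split or share their reads.

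The alternatives fixed in advance were other scalings (DESeq2 1.42.0 size factors, library totals, upper quartile, and TMM without the 100 most abundant genes), other filters (none, or 10 CPM), and other size rules (1.5-fold, the interval bound beyond 2-fold, or more than 4 robust SD from genes of similar level). The deeper library was also thinned to the total of the shallower. Lists were recomputed with other filters, from summed CPM, and without members shared between lists. Removal of the trend with transcript length (lowess), processed pseudogenes left out, protein-coding genes alone and random lists matched on length too were added after seeing the data. Pseudogenes were matched to protein-coding transcripts with BLAST 2.17.0. The rule for reads shared with them was replaced after its result was seen, because the first rule, which that result had met, in part restated the pattern. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and R 4.3.3 were used.

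The steps were tested on simulated data drawn from the means and sizes of these 2 libraries. With counting noise alone, 0 of 14349 unchanged genes met the 2-fold rule, and all of 50 genes were recovered at each of 4 changes (2.4-fold and 4.8-fold, higher and lower). In that setting, the only one in which lists were tested, 4% of 400 random lists without a shift stood apart. With an assumed coefficient of variation between animals of 0.2, 1.91% of 14342 unchanged genes met it, and with 0.4, 23.5% of 14236. Recovery of 2.4-fold changes fell to 78% (higher) and 64% (lower) at 0.2 and to 66% and 70% at 0.4, and that of 4.8-fold changes was 100% in both directions at 0.2 and 96% and 94% at 0.4.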

Results

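Messenger RNA from the lungs of C57BL/6 mice, an inbred laboratory strain, was sequenced to compare exposed with unexposed animals. The exposure was to PM2.5, the fraction of airborne particles of up to about 2.5 micrometres in diameter. There was 1 control library and 1 PM2.5 library, and the labels do not give the sex, the dose, the route of exposure or the number of animals behind each library. Both titles carry the number 12 followed by W, which the labels do not spell out. The control library held 62788045 counts over 21280 gene identifiers with at least 1 count, and the PM2.5 library 57435027 over 23531. The difference between these libraries has no replicate check: ratios carry an exact 95% interval for counting error only, and they describe these 2 libraries, not the conditions.

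The PM2.5 library differed from the control library in genes of xenobiotic metabolism, neutrophils, airway secretion, fat tissue, extracellular matrix, endothelium, cell division and the circadian clock. Among 14518 genes with a mean of at least 1 CPM, the count relative to the scaled library size, 1053 were at least 2-fold higher in the PM2.5 library and 877 at least 2-fold lower, each with a counting interval that excluded equality. These make 13.3% of the genes, and 54.6% of them were higher. That share depended on the settings: it was 77.6% with library totals and 69.2% with the upper quartile, which raised all log2 ratios by 0.23 and 0.14, and 73.7% without a filter. It fell below 50%, to 33.0% at a mean of at least 10 CPM, 43.8% at a size of 1.5-fold and 48.9% among protein-coding genes, the last an alternative chosen after seeing the data. The median log2 ratio was -0.09, with quartiles of -0.48 and 0.33. Across genes, which are not independent replicates, the log2 ratio was lower for longer transcripts (Spearman's rho = -0.37) and for genes of higher mean CPM (rho = -0.35). Its median was 0.38 in the decile of the shortest genes, with a median length of 968 nt, and -0.45 in that of the longest, with a median of 8293 nt. In simulated libraries with an assumed coefficient of variation between animals of 0.2, 1.91% of unchanged genes met the 2-fold rule, and with 0.4 it was 23.5%. The counts of genes therefore cannot be set against the variation between animals.

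**Figure D1:**
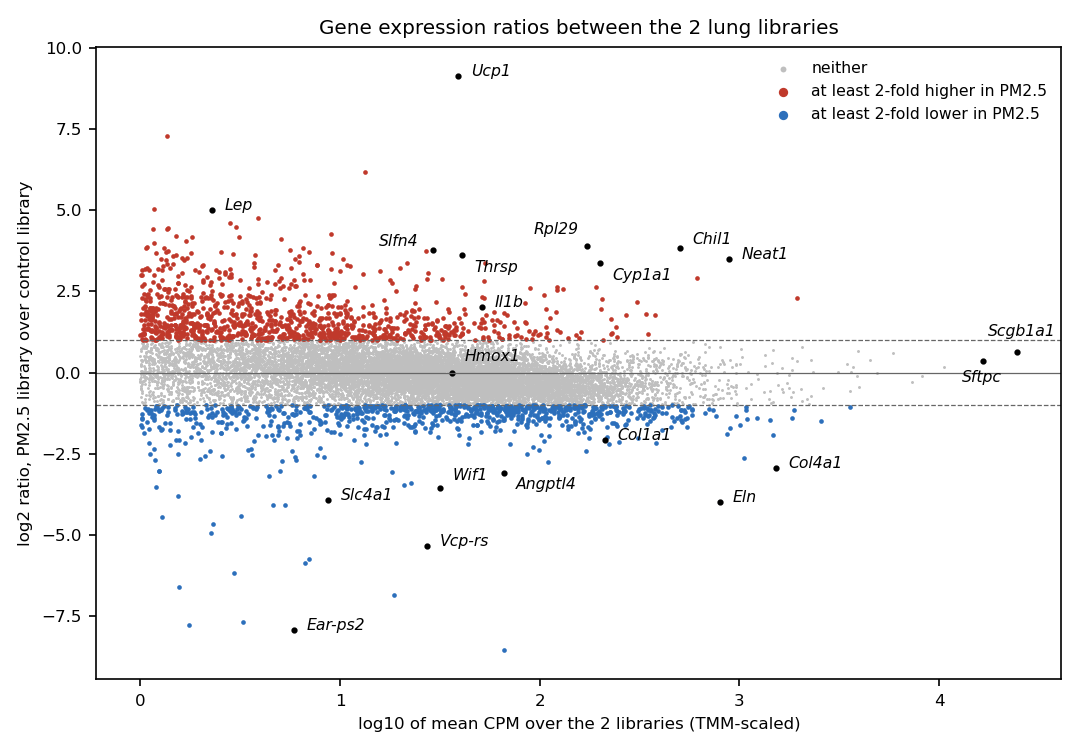
Log2 ratio of the PM2.5 library over the control library (vertical axis) against the mean of both libraries in CPM (horizontal log axis), 1 point per gene of at least 1 CPM. Genes at least 2-fold higher or lower are coloured (1053 and 877), a selection is named, and Ccl21b, without a count in the control library, is not drawn.

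Of 51 gene lists, 47 had at least 5 measured genes and were ranked against 10000 random lists of the same size and expression level. A list is said to stand above or below the random lists where its median log2 ratio lay outside their central 95%. This was so for 25 lists above and 8 below. About 2.35 of 47 would be placed there by chance if lists were random draws, and more because the genes of a list vary together. Scaling shifts all medians alike and leaves these ranks in place, so medians near 0 carry no firm direction. Those of the alveolar macrophage, lysosome and lipid-laden phagocyte, dendritic cell, alveolar type 2, smooth muscle, fatty acid synthesis and histone lists are negative here and positive with library totals or the upper quartile, and that of the T cell list is negative with DESeq2 size factors. Within a list, a gene is counted as higher or lower at 1.5-fold or more with an interval excluding equality.

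**Figure D2:**
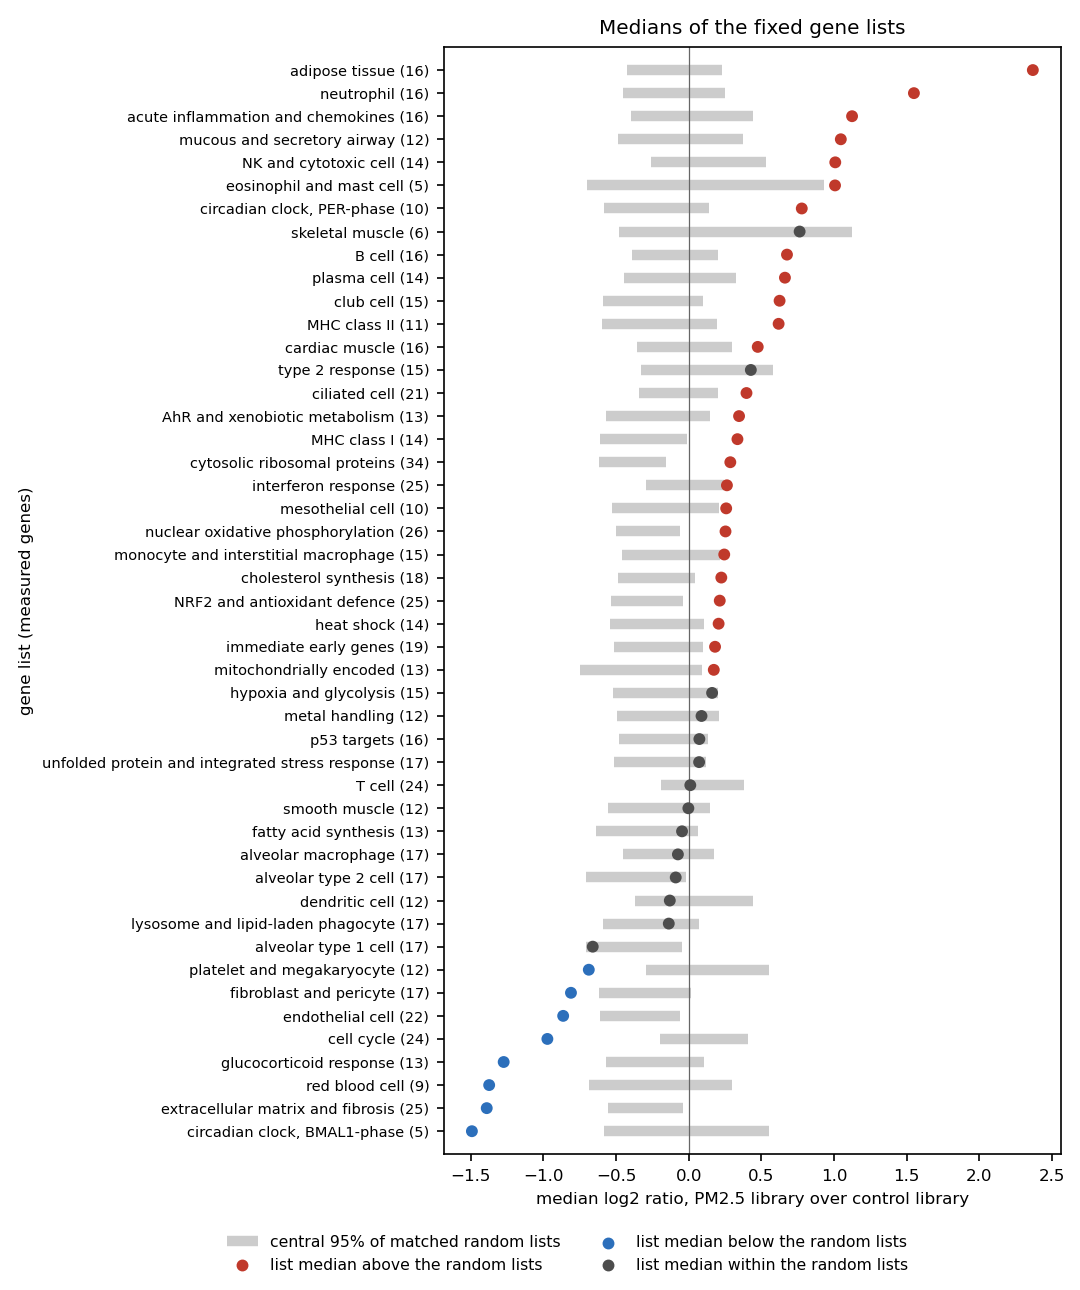
Median log2 ratio, PM2.5 over control, of the measured genes in each of the 47 ranked lists (points, number of genes in brackets), with the central 95% of 10000 random lists matched on expression (grey bars). The adipose list has the highest median at 2.37, and the BMAL1-phase clock list the lowest at -1.49.

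Cyp1a1, the classical target of the aryl hydrocarbon receptor (AhR), and some other genes of xenobiotic metabolism were higher in the PM2.5 library. Cyp1a1 (ENSMUSG00000032315, GRCm38 chromosome 9, 57687928 to 57703824, plus strand) had 2033 counts in the control library and 22711 in the PM2.5 library, a 10.4-fold higher level (95% counting interval 9.95 to 10.9). Cyp2a5 was 5.27-fold higher (5.02 to 5.53), Cyp1b1 2.28-fold (2.09 to 2.48) and the quinone reductase Nqo1 2.18-fold (1.92 to 2.47). Of 13 measured genes of the AhR list, 5 were higher and the receptor gene Ahr itself was 2.99-fold lower. The other 7 met neither size, among them Tiparp, Cyp2s1, Ugt1a6a and Cyp2b10 with ratios of 0.809, 0.983, 1.06 and 0.981. The list median of 0.35 stood above the random lists. The antioxidant (NRF2) list also stood above them, with a median of 0.21, but 19 of its 25 genes met neither size. The 5 higher genes included glutathione reductase, Gsr, at 2.96-fold (2.82 to 3.11), Gsta4 at 1.68-fold and Gpx2 at 1.65-fold, while extracellular superoxide dismutase, Sod3, was 1.93-fold lower. Haem oxygenase, Hmox1, was within counting error of equality under this scaling, with 2132 and 2260 counts and a ratio of 0.988 (0.931 to 1.05). The metal handling list stayed within the random lists at 0.09, with 1 gene higher and 2 lower of 12. Its ferritin genes Fth1 and Ftl1 had ratios of 1.07 and 1.02. The metallothionein Mt2 was 2.47-fold lower (2.27 to 2.69), and Mt1 had a log2 ratio of -0.25.

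Neutrophil genes were higher as a group. Of 16 measured genes, 13 were higher, among them the receptor of granulocyte colony-stimulating factor Csf3r at 3.93-fold (3.81 to 4.06), the calprotectin subunits S100a8 and S100a9 at 3.46-fold and 3.43-fold, and Padi4 at 3.82-fold. The median log2 ratio was 1.55, against -0.45 to 0.25 for the central 95% of random lists. Red blood cell transcripts were lower, with a median of -1.37, and whether the amount of blood in the tissue bears on the neutrophil genes was not tested. Among genes for neutrophil granule proteins, Camp and Ngp were 2.80-fold and 3.36-fold lower, whereas Ltf and Mmp8 were 3.42-fold and 2.19-fold higher. In the list of acute inflammation and chemokines, 10 of 16 genes were higher and 1 lower, with a median of 1.12. Il1b was 4.04-fold higher (3.79 to 4.30), Ccl7 5.92-fold (3.79 to 9.63), Tnf 3.98-fold (2.81 to 5.77), and Ccl2, with 27 and 116 counts, had an interval of 2.62 to 6.33. The acute-phase gene Saa3 rested on 129 and 179 counts, a ratio of 1.29 (1.03 to 1.63). Cxcl1, below a mean of 1 CPM and so not among the 16, had 5 and 70 counts, a ratio of 13.0 (5.33 to 41.4). Cxcl2, Cxcl3, Cxcl5 and Il6, also below it, had ratios of 1.59, 1.17, 1.01 and 1.18 with intervals that include equality. Only 10 of the 16 genes reached 1 CPM in the control library. The other members, Tnf, Ccl2, Ccl3, Ccl4, Ccl7 and Csf2, entered through the PM2.5 library, and all were counted as higher. Most of the 10 higher genes were rare transcripts. The summed CPM of the list had a log2 ratio of -0.0031, set by the abundant Icam1 and Nfkbia. With members of at least 1 count the median was 0.65 and the list no longer stood above the random lists.

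Among macrophage and other myeloid lists, the alveolar macrophage list lay within the random lists at -0.07, with 3 genes higher and 2 lower of 17. Its abundant members included Chil3 with a ratio of 1.15 and the mannose receptor Mrc1, 1.62-fold lower, while the scavenger receptor Marco was 3.57-fold higher. The list of lysosome and lipid-laden phagocyte genes was also within them at -0.14, with 4 higher and 3 lower of 17. Its most abundant gene Cd36 was 1.51-fold lower, and osteopontin, Spp1, was 10.3-fold higher with 542 and 6010 counts. Monocyte and interstitial macrophage genes stood above the random lists at 0.24, with 6 of 15 higher, including Ly6c2 at 1.83-fold and Ms4a7 at 1.87-fold, and 3 lower. The sum of that list pointed the other way, at -0.88, because Ace, which lung capillaries also express, was 2.66-fold lower, and the list no longer stood apart from random lists matched on transcript length too. Eosinophil and mast cell genes were few, with 3 of 5 higher and 1 lower, a median of 1.01 and a summed log2 ratio of -0.88. With the 13 members of at least 1 count, the median was 1.01 and the list no longer stood above the random lists. The mast cell protease Mcpt4 was 6.81-fold higher (4.39 to 11.0) on 23 and 168 counts. Type 2 response genes lay within the random lists at 0.43, with 5 higher and 1 lower of 15. Dendritic cell genes did so at -0.13, with 2 higher and 2 lower of 12 and a ratio of 0.969 for Irf8.

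Lymphocyte lists differed from one another. In the list of natural killer (NK) and cytotoxic cells, 11 of 14 genes were higher and none lower, with a median of 1.01. Its receptor genes Klra8 and Klrd1 were 4.88-fold and 3.52-fold higher, and the granzyme gene Gzmb 3.46-fold. Of 16 B cell genes, 10 were higher and none lower, with a median of 0.68, and they included Cd72 at 3.21-fold and Cr2 at 2.64-fold. Plasma cell genes had a median of 0.66, with 8 of 14 higher and none lower. The immunoglobulin heavy chain genes Ighg3, Ighg2c and Ighg1 were 27.1-fold (16.5 to 47.8), 6.72-fold and 6.15-fold higher. The T cell list lay within the random lists at 0.01, with 4 higher and 2 lower of 24. The NK, B cell and plasma cell lists stood above the random lists, as did MHC class II at 0.62, where 6 of 11 genes were higher, H2-Ob 2.15-fold and H2-Aa 1.83-fold. The MHC class I list did so at 0.34, although 10 of its 14 genes met neither size. Its leading genes H2-Q7 at 6.24-fold and H2-Q6 at 3.92-fold are close copies that share reads, so their separate values are uncertain. Interferon response genes stood above the random lists at 0.26, with 6 higher and 2 lower of 25. Oas2 was 5.23-fold and Mx1 3.05-fold higher, but the list no longer stood apart among members of at least 10 CPM, with a median of 0.09.

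Of the lists for airway epithelium, the secretory, club cell and ciliated cell lists stood above the random lists. In the mucous and secretory list, 9 of 12 genes were higher, with a median of 1.05. The host defence protein gene Bpifa1 was 7.56-fold higher (7.39 to 7.74), the antimicrobial lectin Reg3g 3.60-fold (3.41 to 3.80), Agr2 4.42-fold (3.39 to 5.85) and Gp2 11.1-fold (6.64 to 19.8). The gel-forming mucin Muc5ac was the gene that went the other way, with 77 and 51 counts and a log2 ratio of -0.70 (-1.24 to -0.17). Of 15 club cell genes, 8 were higher and none lower, with a median of 0.63. Scgb3a1 was 3.51-fold higher and Krt15 6.94-fold. The club cell secretoglobin Scgb1a1 was 1.54-fold higher and alone took 1.79% of the control counts and 3.24% of the PM2.5 counts. Ciliated cell genes had a median of 0.40, but 18 of 21 met neither size, and the 3 higher were led by the dynein light chain gene Dynlrb2 at 2.52-fold. The basal cell list had 3 measured genes and was not ranked. Its aquaporin Aqp3 was 1.97-fold higher, and the list median was 0.22.

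Alveolar epithelial lists stayed within the random lists. The type 2 cell list had a median of -0.09, with 2 genes higher and 6 lower of 17. Surfactant protein C, Sftpc, was 1.29-fold higher and Sftpb 1.39-fold lower. The 1 large exception was Chil1, a chitinase-like protein gene (ENSMUSG00000064246, chromosome 1, 134182176 to 134190181, plus strand), 14.4-fold higher (13.9 to 14.9) with 3794 and 58618 counts. The type 1 cell list had a median of -0.66, with 1 gene higher and 9 lower of 17. That median was lower than those of all but 4.79% of the random lists. Ager was 1.41-fold lower and Clic5 1.75-fold lower.

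Extracellular matrix genes were lower in the PM2.5 library. Of 25 measured genes, 21 were lower, and the list median of -1.39 lay below the central 95% of random lists, -0.56 to -0.04. Elastin, Eln (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323, minus strand), was 15.7-fold lower (15.3 to 16.1), with 86673 and 5932 counts. The cross-linking enzyme gene Lox was 5.32-fold lower, the membrane protease gene Mmp14 5.21-fold, fibrillin Fbn1 4.55-fold and collagen Col1a1 4.20-fold (4.07 to 4.33). The basement membrane collagen Col4a1 (ENSMUSG00000031502, chromosome 8, 11198423 to 11312826, minus strand) was 7.70-fold lower with 156494 and 21810 counts. Lum, Timp1 and Cthrc1 went the other way, 2.70-fold, 2.52-fold and 2.28-fold higher. Long transcripts were lower in general, and with the length trend removed, an alternative chosen after seeing the data, the matrix median was -1.21. Fibroblast and pericyte genes stood below the random lists at -0.81, with 9 of 17 lower, including Mfap4 at 3.24-fold and Pdgfrb at 3.28-fold. Dcn, Pi16 and Inmt were higher, by 2.68-fold, 1.96-fold and 1.74-fold.

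Endothelial genes were lower as well, with 16 of 22 lower, none higher and a median of -0.86. The junction gene Cdh5 was 3.05-fold lower, the apelin receptor gene Aplnr 3.03-fold, Ptprb 2.76-fold and the VEGF receptor gene Kdr 2.59-fold. Smooth muscle genes lay within the random lists at -0.00, with 4 higher, such as Tagln at 2.02-fold and Acta2 at 1.60-fold, and 1 lower of 12. The mesothelial list stood above the random lists at 0.26 with 1 of 10 genes higher, Wt1 at 1.53-fold, but not above those matched on transcript length too.

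Transcripts typical of fat tissue were higher, with the highest median of the ranked lists. Of 16 measured genes, 13 were higher and 2 lower, and the list median was 2.37, against -0.42 to 0.23 for the random lists. Ucp1, the uncoupling protein of brown fat (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452, plus strand), had 8 counts in the control library and 4855 in the PM2.5 library, a ratio of 566 (287 to 1311). The adipokine genes Lep and Retn were 32.2-fold (16.1 to 75.2) and 11.4-fold higher, and the lipid droplet gene Cidea 12.7-fold. Among the abundant members, Car3, Fabp4 and Cfd were 6.01-fold, 6.08-fold and 5.82-fold higher, while the lipase genes Lipe and Pnpla2 were 1.60-fold and 1.65-fold lower. The summed CPM of the list, from 432 to 1056 CPM, had a log2 ratio of 1.29, below the median. In the control library, 13 of the 16 genes were at 1 CPM or more, and 1 is also in the alveolar macrophage list. The lipid metabolism genes Thrsp and Pnpla3, 12.4-fold and 17.4-fold higher, moved beside these fat markers. The fatty acid synthesis list, which includes Thrsp, lay within the random lists at -0.05, with 4 higher and 1 lower of 13, Scd1 at 1.61-fold higher and Fasn at 1.54-fold lower. The cholesterol synthesis list stood above them at 0.22, with 4 of 18 higher, led by Msmo1 at 1.68-fold, and 2 lower.

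Markers of muscle also differed. Cardiac muscle genes, which mice also express around the pulmonary veins, stood above the random lists at 0.48 with 7 higher and 3 lower of 16. Nppa, Tnnt2 and Sln were 2.79-fold, 2.27-fold and 2.21-fold higher, while the myosin genes Myh6 and Myh7 were 2.61-fold and 2.19-fold lower. The summed CPM of the cardiac list had a log2 ratio of 0.02. Skeletal muscle genes had a median of 0.76, within the random lists, with 4 of 6 higher, including Tnnt3 at 9.53-fold. The list for thyroid, thymus and oesophagus had 3 measured genes and was not ranked. Its median was 0.55, with Tg 2.80-fold higher on 32 and 96 counts.

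Red blood cell transcripts were lower, with 8 of 9 genes lower and a median of -1.37. Slc4a1, the anion exchanger of the red cell membrane, was 15.2-fold lower (11.9 to 19.8) with 952 and 67 counts, and the haem synthesis gene Alas2 2.64-fold lower. The haemoglobin copies Hba-a1 and Hba-a2, which are nearly identical, went opposite ways, 3.79-fold lower and 3.14-fold higher, so their separate values are uncertain. Platelet and megakaryocyte genes had a median of -0.69, with 6 lower, such as Itga2b at 2.45-fold, and 2 higher of 12. They stood below the random lists, but not among members of at least 10 CPM, where the median was -0.43.

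Cell cycle genes were lower, with 19 of 24 lower, none higher and a median of -0.97. The proliferation marker Mki67 was 2.92-fold lower (2.71 to 3.16), Cenpf 4.99-fold and the cyclin gene Ccnb2 3.21-fold. At 10 CPM or more 7 genes of the list remained, with a median of -0.35 within the random lists. The 4 replication-dependent histone genes measured were not ranked and had a median of -0.10.

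Clock genes of opposite phase differed in opposite directions. All 5 genes of the BMAL1-phase list were lower, with a median of -1.49, Npas2 6.51-fold (5.26 to 8.13), Arntl 2.92-fold, Nfil3 2.81-fold and Cry1 2.72-fold. In the PER-phase list 7 of 10 were higher, with a median of 0.78, including Ciart at 5.23-fold, Per3 at 2.75-fold and Dbp at 2.44-fold, and Per1 was 1.62-fold lower. The labels do not give the time of day at which the lungs were taken. Genes that respond to glucocorticoids stood below the random lists at -1.27, with 11 of 13 lower. Angptl4 was 8.46-fold lower, Zbtb16 3.57-fold and Pdk4 3.45-fold, whereas Lcn2 was 1.55-fold higher. Of these 13 genes, 4 are also in other lists.

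Stress and housekeeping lists moved little. Immediate early genes stood above the random lists at 0.18, with 6 higher and 2 lower of 19, Atf3 at 2.57-fold and Fosb at 2.22-fold. Their summed CPM had a log2 ratio of -0.16, and the list did not stand apart when random lists were matched on length too. Heat shock genes stood above the random lists at 0.21 with 2 higher and 1 lower of 14, Hspe1 at 1.87-fold. Unfolded protein and integrated stress response genes, at 0.07 with 3 higher and 2 lower of 17, lay within the random lists. So did p53 targets, at 0.07 with 2 higher and 2 lower of 16, and hypoxia and glycolysis genes, at 0.16 with 3 higher and 1 lower of 15. In these 3 lists Hspa5 was 1.33-fold higher, Btg2 had a ratio of 1.01 and Vegfa was 1.74-fold higher. Genes for oxidative phosphorylation stood above the random lists, with medians of 0.25 for those of the nucleus (8 of 26 higher) and 0.17 for those of the mitochondrial genome (1 of 13 higher). The cytosolic ribosomal protein list had a median of 0.29, with 1 of 34 genes higher, Rpl38 at 1.62-fold. The mitochondrially encoded and ribosomal lists did not stand apart from random lists matched on length too.

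Other genes at the extremes belong to none of these groups. Among the highest were Ccl21b, with 0 and 185 counts, and Tnfsf13os, with 1 and 168 counts and a ratio of 157 (27.7 to 6221). Ccl21b was 57.5-fold higher against a floor of 3 counts in the control library, and its counting interval began at 46.3-fold. Ccl21b has close copies and Tnfsf13os lies antisense to another gene, so both are uncertain. Slfn4, a myeloid gene of the Schlafen family, was 13.6-fold higher, Gpr17 18.1-fold, Tmem221 14.2-fold, Tmem45b 13.7-fold and Larp1b 21.4-fold on 7 and 161 counts. The nuclear RNA Neat1 was 11.2-fold higher (11.0 to 11.5) and Snhg11 13.6-fold. Among the lowest were the Wnt inhibitor gene Wif1 at 11.7-fold, the protease genes Ctse at 11.1-fold and Adamts17 at 10.5-fold, Grik3 at 25.3-fold, Stk32c at 9.16-fold and Lrrc4b at 9.16-fold. Of the sex-linked genes, the Y-linked Ddx3y had 4032 and 4322 counts and Xist 8 and 63. The list of 4 measured genes was not ranked and had a median of 0.20.

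Several of the lowest values came from pseudogenes, whose reads resemble those of other genes. Ear-ps2 had 681 and 3 counts, a ratio of 244 in favour of the control library (83.0 to 1184), and Tmem181c-ps was 21.8-fold lower. Rps24-ps3 and Vcp-rs were 58.2-fold and 40.6-fold lower. Of 92 processed pseudogenes measured, 10 were at least 8-fold lower, or 10.9%, against 0.116% of protein-coding genes. The ribosomal protein gene Rpl29, 14.8-fold higher with 1267 and 20165 counts, matched the pseudogene Gm13841 at 99.4% identity. That pseudogene had 7687 and 22 counts, and with both added the log2 ratio was 1.07 in place of 3.89.

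**Figure D3:**
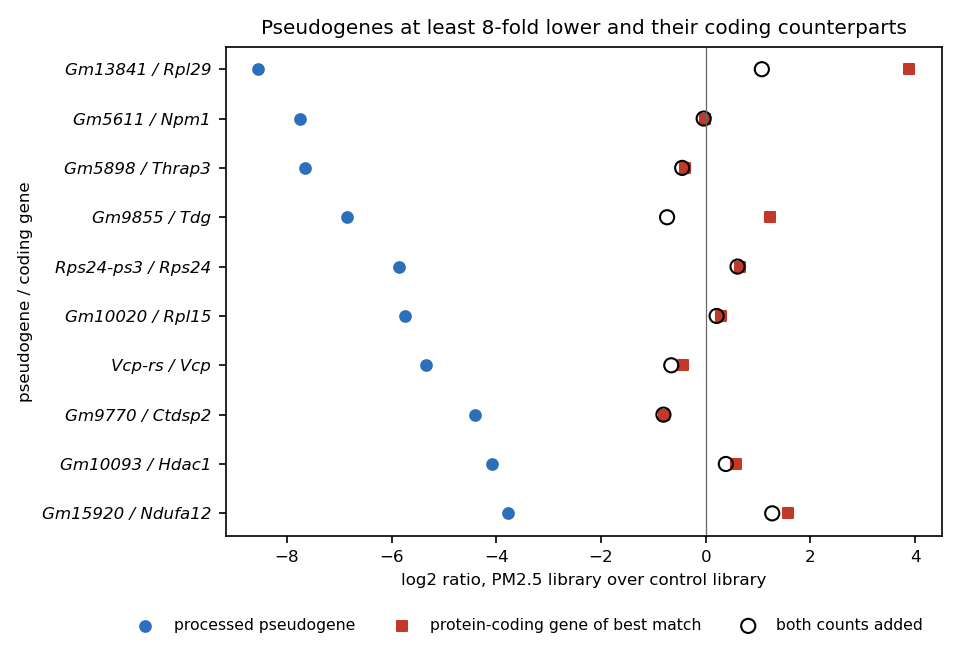
Log2 ratio, PM2.5 over control, of the 10 processed pseudogenes at least 8-fold lower (circles), the protein-coding gene of best sequence match (squares) and both counts added (open circles). None of the 10 coding genes is 2-fold lower, and for Rpl29 the sum lies at 1.07.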

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

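The length trend, the pseudogene and protein-coding restrictions and the random lists matched on length were tests chosen after the results were seen; the others were planned. No paired analysis was possible because there is 1 library per group. Against 1053 genes higher and 877 lower, the count lower became 444 with library totals (1541 higher) and 578 with the upper quartile (1297 higher), by construction of a shift in all ratios. Without a filter 3229 genes were higher (1155 lower), and at 10 CPM or more 310 were higher (630 lower). Different numbers of genes were tested there, and log2 ratios were lower for genes of higher mean CPM (Spearman's rho = -0.35 across genes of at least 1 CPM). A size of 1.5-fold gave 2163 higher and 2776 lower, and more than 4 robust SD gave 107 and 47, by the sizes themselves. Other settings stayed within 1.5 times of the main counts: DESeq2 size factors (1033 and 910), the interval bound beyond 2-fold (750 and 624), the thinned library (1064 and 856), the length trend removed (1018 and 674), no processed pseudogenes (1044 and 864) and protein-coding genes (812 and 847). With the length trend removed the genes themselves changed: 900 of the 1053 higher and 575 of the 877 lower genes kept their call. Lists standing below the random lists numbered 5 in place of 8 at 10 CPM or more. The platelet and cell cycle lists lay within the random lists there. The BMAL1-phase clock list had under 5 members left and was not ranked, nor was the NK and cytotoxic list. Among lists that stood apart, signs reversed with summed CPM in acute inflammation (-0.0031), monocytes (-0.88), eosinophils and mast cells (-0.88) and immediate early genes (-0.16), where abundant members outweigh the others. Of the other values of list medians, 297 kept direction and side, 38 of summed CPM, which were not ranked, kept direction, 10 no longer stood apart and 2 newly did; the cause was not tested. Another 19, of 9 lists that did not stand apart, turned sign: 6 with library totals, 6 with the upper quartile, 5 with summed CPM, 1 with DESeq2 size factors and 1 at 10 CPM or more. No gene named by rank or fixed by name in advance changed its 2-fold call with the other scalings, and Hmox1 and Ddx3y, near equality, turned sign with library totals and the upper quartile. For the genes named by rank, which lie far beyond 2-fold, shifts of at most 0.23 could not change a call. Depth limits rare transcripts, such as Cxcl1 with 5 control counts, where the interval of the ratio spans 5.33 to 41.4.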

Other observations

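Several classes of noncoding transcripts were higher in the PM2.5 library. Of 85 long intergenic RNAs measured, 31 were at least 2-fold higher and 4 lower, with a median log2 ratio of 0.66. Of 120 antisense genes, 56 were higher and none lower (median 0.82), and of 110 genes annotated as processed transcripts 47 were higher and 1 lower (median 0.78). These medians lay above those of random lists matched on expression level. Protein-coding genes had a median of -0.11. Processed pseudogenes, also noncoding, had a median of 0.08, within the random lists, with 9 of 92 at least 2-fold higher and 13 lower. The nuclear RNA Malat1 had 37544 and 200013 counts (log2 ratio 2.31), and the imprinted RNA Meg3 was higher with a log2 ratio of 3.03, as was Firre at 2.64. Such values were not confined to noncoding genes: the protein-coding genes Leng8, Ogt and Rsrp1 had log2 ratios of 2.63, 2.26 and 2.18. These genes, and Nlrp1a, Nlrp1b and Nnt below, were chosen after their values were seen, and antisense values are uncertain because the strand setting of the counting is not given in the sources used here.

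Immunoglobulin variable segments, which lie outside the fixed lists, were higher too: of 46 measured, 19 were at least 2-fold higher and none lower, with a median of 0.90. The inflammasome sensor genes Nlrp1a and Nlrp1b, which are close copies, had log2 ratios of -3.03 and 3.15. The mitochondrial transhydrogenase gene Nnt, which differs between C57BL/6 substrains, had 3480 counts in the control library and 1113 in the PM2.5 library (log2 ratio -1.75). Genes on the Y chromosome, 5 measured, had a median log2 ratio of 0.40.

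Of the tests on the 3 patterns below, those of a trend with transcript length, a lower share of fibroblasts and shared reads were chosen after the results were seen. The test of fat tissue was aimed at the adipose pattern, already seen, with its limits set before the further fat genes were looked at. The first pattern is the adipose list, with a median of 2.37. Its lowest median over 4 scalings was 2.35. The scalings differ by a shift of all log2 ratios alike, at most 0.23 from the main one. None of them could therefore remove a median of this size, and the result was settled by the size of the shifts. Fat tissue taken along with the lung may contribute. To test it, 40 further fat genes were listed beforehand, and other fixed lists also hold Pparg, Fasn and Acaca among them. By intervals that exclude equality, as those of 83.0% of all measured genes do, 18 of the 32 measured were higher and 9 lower. The median of these 32 was 0.61, above all random lists. That is below the 1.0 set in advance as evidence for such fat tissue and above the 0.3 set against it. Many of these genes are also expressed by lung cells, which limits how far added fat could raise them. Abundant ones, such as Fasn and Ces1d at 538 and 735 CPM in the control library, had log2 ratios of -0.62 and -0.22. Mgst1, at 212 CPM, went the other way at 0.65. Rare ones, such as Ebf2 and Lgals12 at 0.483 and 2.9 CPM, had 1.81 and 1.04, but Ppara at 2.43 CPM had -0.02. The limit of 1.0 could therefore be missed with fat tissue present, and no conclusion is drawn from this test. The adipose list had a log2 ratio of 1.29 in summed CPM, with 6.01-fold for Car3, 6.08-fold for Fabp4 and 5.82-fold for Cfd. Lung cells responding to the exposure cannot be told apart from such fat tissue with 1 library per group.

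The second pattern is the lower level of extracellular matrix genes. A trend with transcript length does not account for it: after its removal the median was -1.21, below each of 10000 random lists matched on level and length, of which the lowest was -0.69. A lower share of fibroblasts stays open: matrix genes lay 0.84 below the other fibroblast and pericyte genes (difference -0.84, 95% bootstrap interval over genes -1.61 to 0.00), whose median was -0.55 and which went both ways. Genes of a list vary together, so that interval describes the spread among these genes and not the variation between animals. The exposure and any other difference between the animals cannot be told apart, with 1 library per group.

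The third pattern is the 10 processed pseudogenes at least 8-fold lower, which match coding genes at a median identity of 99.3%. Reads shared with these coding genes and assigned differently in the libraries are a candidate explanation that the tables do not decide. Of the 10 coding genes, 0% were 2-fold lower (exact 95% interval 0 to 30.8%), against 6.14% of all protein-coding genes. The rule for shared reads asked for an interval below that share. With 10 genes it cannot be met even at 0%, so no conclusion is drawn from it. Of the same genes 3, Rpl29, Tdg and Ndufa12, were 2-fold higher, against 5.89% of all protein-coding genes. By intervals that exclude equality, as those of 83.0% of all measured genes do, 6 of the 10 coding genes were higher, 3 lower and 1 neither. Their median was 0.44, and with the counts of both genes added the pairs ranged from -0.81 (Ctdsp2) to 1.27 (Ndufa12). A genetic difference between the animals stays open as well, with 1 library per group.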
